A study of Mus musculus with 4 samples.

How the data were processed

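RNA was taken from the lumbar (L4-6) spinal cord of male C57BL/6J mice, and strand-specific libraries were made after poly(A) selection and sequenced as read pairs of 150 bases on an Illumina HiSeq4000, per the labels' protocols. The reads were trimmed with Trimmomatic 0.30, aligned with HISAT2 2.0.1 to the mouse genome build mm10 and counted with featureCounts, per the submitters' processing notes. The gene annotation, the strand setting and whether reads or read pairs were counted are not given in the sources used here, so that counts of overlapping and antisense genes and of close paralogues are uncertain. The deposited files hold raw counts per Entrez gene identifier, 1 file per library, not normalized, as the whole-number values and the file headers show. Whether each library came from a single animal or from a pool is not given in the sources used here. One of the 4 files held identifier and count joined by a literal backslash and letter in place of a tab, and it was split there. The counts summed to between 32936609 and 39461573 per library, with a mean of 36.8 M, while the labels give 33.6 M reads per sample on average.

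The 4 samples were grouped by their titles into 2 labelled cuff and 2 labelled sham. The names of the deposited files carry the opposite condition for each of them, and this conflict could not be settled from the sources used here. Replicate numbers came from the titles. All 6 pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom between 25.4 and 72.7), so no library was a copy of another. Of 27179 identifiers, 25275 were matched to symbols in a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 names, 17 more through GENCODE M21, and 1887 had no match. Coordinates are 1-based and come from the RefSeq table.

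Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with filterByExpr by group, which left 16918, and libraries were scaled by the trimmed mean of M values (TMM). The 2 groups were compared with edgeR's quasi-likelihood F test (robust, two-sided, group as the only term), and genes with a Benjamini-Hochberg adjusted p under 0.05 are called here. The common biological coefficient of variation was 0.152. CPM values use the TMM-scaled totals of the tested genes and are given as mean ± SD over 2 libraries, log2 fold changes as labelled cuff minus labelled sham. Their standard errors are the absolute unshrunk coefficient divided by the square root of F. With 2 libraries against 2, permutation of the labels allows 3 splits and no share under 0.05, so the tests rest on the model's sharing of spread across genes.

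The design, the test, the alternatives, 40 gene lists, a panel of 24 genes and the rule for named genes were fixed before the data were examined. None of the lists was chosen on these samples. The rule named the 12 genes with the largest absolute log2 fold change in each direction among called genes with non-overlapping groups, a mean CPM of at least 1 and a symbol that is not a clone or pseudogene name. It also took up to 4 members with the smallest p of each list with a call, up to 2 of other lists, the panel, and the 5 genes with the highest mean CPM. Other genes named in a list or a count were added after their values were seen. Lists were tested with camera at the preset correlation of 0.01 and again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 40 lists. Camera called 16 lists, 11 higher and 5 lower, camera with an estimated correlation 0 (smallest adjusted p = 0.84, smallest unadjusted p = 0.0381) and fry 0 (smallest adjusted p = 0.226).

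The steps were tested on counts simulated from the means, library sizes and dispersions of these libraries, with 200 genes of at least 1 CPM changed, for the comparison of labelled cuff with labelled sham. Over 16694 genes, the test recovered 25.4% of the genes changed 1.5-fold, 74.6% of those changed 2-fold and 97.0% of those changed 4-fold, and called 25 unchanged genes. With the length and GC trends of these libraries added to the simulation (16711 genes) it called 70 unchanged genes, 55 of them lower.

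The alternatives fixed beforehand were RLE (median-ratio) and upper quartile scaling, DESeq2, limma-voom, edgeR's likelihood ratio test, a dispersion prior that is not robust, no filter, a mean count of at least 10, the replicate number as a block, each library left out, and a fit without the genes of other cell types and mitochondria. Chosen after seeing the data were a correction of each library for transcript length and GC content (a local regression over the longest GENCODE M21 transcript of 15464 genes, used as offsets), alone, with the likelihood ratio test or with the replicate block, a corrected test with the prior degrees of freedom of the uncorrected fit, the mean of the Schwann cell list as a covariate, and the fit of genes with a transcript length only.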

Results

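The data were 4 poly(A) RNA-seq libraries from the lumbar (L4-6) spinal cord of male C57BL/6J mice. The sample titles put 2 libraries in a sciatic nerve cuff group and 2 in a sham group, and the series design gives 28 days after surgery. A cuff placed around the sciatic nerve constricts it and is used as a model of persistent neuropathic pain, and a sham operation exposes the nerve without the cuff. Gene counts summed to 36074864 and 32936609 in the libraries labelled cuff (replicates 1 and 2) and to 39461573 and 38823517 in those labelled sham. The names of the deposited files give the opposite condition to the sample titles for all 4 libraries. Groups were taken from the titles, so each direction below is that of the libraries labelled cuff against those labelled sham, and every direction would turn round if the file names were right. No label says that the libraries came from different animals, so the p-values measure only the spread between these libraries.

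Of the 5 genes with the highest mean CPM, 4 were mitochondrially encoded and 1 was a myelin gene. The mitochondrial gene mt-Co1 averaged 26466 ± 3827 CPM (counts relative to library size, mean ± SD, n = 2) in the libraries labelled cuff and 30151 ± 5903 in those labelled sham, and Mbp, which encodes myelin basic protein, averaged 19344 ± 1636 and 17226 ± 2877. The other 3 were mt-Cytb, mt-Nd1 and mt-Nd2, and none of the 5 passed the test between groups (adjusted p from 0.602 for mt-Co1 to 0.923 for mt-Nd2). Across genes, log2 CPM values correlated at Pearson r = 0.983 between the libraries labelled cuff and 0.988 between those labelled sham, and between 0.972 and 0.983 across groups. The first principal component held 56.7% of the variance and placed both libraries labelled cuff on one side, at 12 for replicate 1 and 48.5 for replicate 2, and those labelled sham on the other, at -34.7 and -25.7.

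The comparison asked which genes differed in the lumbar cord 28 days after cuff or sham surgery. Of 16918 genes tested, 696 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). They comprised 195 genes that were higher and 501 that were lower in the libraries labelled cuff, and 60 and 109 of these differed by at least 2-fold. In counts simulated from these libraries, unchanged genes made up more than a 0.05 share of the calls. With no length or GC trend, 25 unchanged genes were called, beside 17, 50 and 64 genes changed 1.5-fold, 2-fold and 4-fold. With the length and GC trends of these libraries, 70 unchanged genes (55 lower) were called, beside 20, 40 and 60 changed genes. The smallest p-value was that of Zbtb16, a zinc finger transcription factor induced by glucocorticoids (mouse mm10 chromosome 9, 48651797 to 48836225). It fell from 57.0 ± 2.03 CPM (SD, n = 2) in the libraries labelled sham to 16.6 ± 2.05 in those labelled cuff, a log2 fold change of -1.78 ± 0.14 (SE, adjusted p = 6.05e-06). Among the higher genes the smallest p-value was that of Cldn5, the tight junction protein of the blood-brain barrier (chromosome 16, 18776847 to 18778262). It rose from 8.27 ± 1.71 to 24.8 ± 1.45 CPM, a log2 fold change of 1.58 ± 0.18 (adjusted p = 0.000307). In all 696 genes the 2 groups did not overlap in CPM, as in 54.1% of all tested genes, where chance gives 33.3%.

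**Figure D1:**
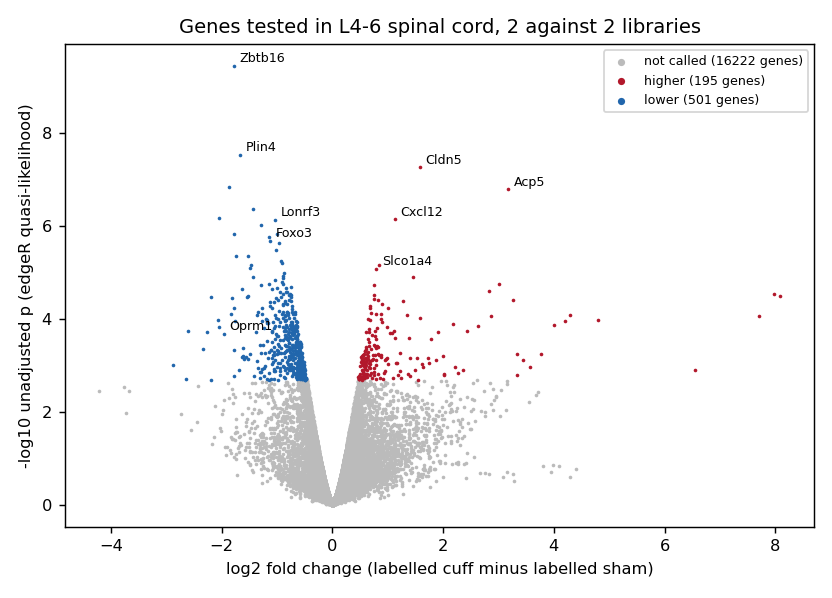
Each point is 1 of the 16918 tested genes, with the log2 fold change (labelled cuff minus labelled sham) on the x axis and -log10 of the unadjusted p on the y axis. The 195 higher genes are red, the 501 lower genes blue and 9 of the named genes are marked. Fitted values above about 6 belong to genes with no count in the libraries labelled sham and depend on the prior count.

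The number of genes depended on single libraries. It was 1928 without the first library labelled cuff (714 higher, 1214 lower), 216 without the second (158 higher, 58 lower), 0 without the first labelled sham and 13 without the second (5 higher, 8 lower), each from 1 library against 2. The excess of lower genes was thus turned round without the second library labelled cuff. These fits also differed in their prior degrees of freedom, the weight given to the spread shared across genes. Their median was infinite without the first library labelled cuff and 15.8 without the second. It was 5.70 without the first labelled sham and 9.45 without the second. The numbers of calls thus cannot be set down to the library left out alone. Abundance also followed transcript composition. The median log2 fold change rose from -0.27 in the 10% of genes with the lowest GC content to 0.28 in the 10% with the highest, and it was -0.27 in the 10% with the longest transcripts. The lower genes had a median transcript length of 6524 nt and a GC content of 42.5%, the higher genes 2970 nt and 56.4%, and all tested genes 3384 nt and 49.9%. With each library corrected for length and GC, edgeR's quasi-likelihood test called 17 genes, 7 higher and 10 lower. The prior degrees of freedom fell from 15.8 to 6.36 in that fit. With those of the uncorrected fit imposed in their place, 795 genes were called (351 higher, 444 lower). The corrected counts did not give that prior, so 795 shows only how far the drop in calls depended on it. Of the 17 genes, 15 were among the 696. They included the lower genes Zbtb16, Lonrf3, Foxo3, Klf15, Klf9, Zbtb38, Tnpo1, Arid5b and Mical3 and the higher genes Slco1a4, Cxcl12, Apcdd1, Acp5 and Cldn5. The other 2 were Neat1 and Slc6a6, both higher.

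**Figure D2:**
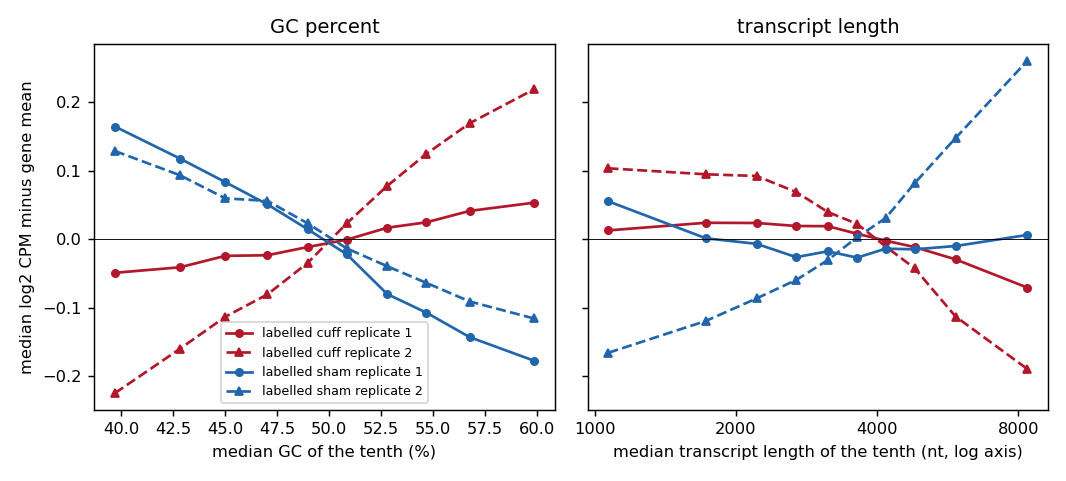
Median log2 CPM relative to each gene's mean over the 4 libraries, for 10 equal groups of the tested genes ordered by GC content (left, percent) or by the length of the longest transcript (right, nt, log axis). Each line is 1 library. In the group with the lowest GC content the second library labelled cuff was at -0.23 and the first labelled sham at 0.16, and the second labelled sham rose to 0.26 in the group with the longest transcripts.

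Among called genes that met the naming rule (mean CPM of at least 1), the 12 largest increases were in genes of low count. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, rose from 0.533 ± 0.199 to 4.85 ± 0.854 CPM (log2 fold change 3.18 ± 0.38, adjusted p = 0.000547). The platelet chemokine gene Ppbp (3.01 ± 0.51, adjusted p = 0.00855) and the neutrophil myeloperoxidase gene Mpo (2.63 ± 0.41, adjusted p = 0.0163) rose too. The other 9 were Asgr1, Nfe2, Haao, Hrc, Wfdc21, Ly6a2, Ly6c2, Ndufa4l2 and Hp, with log2 fold changes from 2.43 for Asgr1 to 1.79 for Hp. Each of these 12 genes had a mean of at most 11.3 CPM in either group. Ly6a2 and Ly6c2 have close paralogues at the same locus, so that their counts are uncertain. After the length and GC correction Acp5 stayed called (adjusted p = 0.046), and the other 11 had adjusted p from 0.0621 for Mpo to 0.156 for Haao. Their log2 fold changes stayed nearly as large, such as 2.99 for Ppbp, 2.38 for Mpo, 2.37 for Asgr1, 2.21 for Haao, 1.91 for Ly6c2 and 1.61 for Hp.

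Grin2a, Oprm1 and Kcnh7 were among the 12 largest decreases by the same rule. Grin2a, a subunit of the NMDA glutamate receptor (log2 fold change -2.34 ± 0.47, adjusted p = 0.0258), was at 2.64 and 7.36 CPM in the libraries labelled sham and at 0.915 and 1.05 in those labelled cuff. Oprm1, the mu opioid receptor gene (chromosome 10, 6758593 to 7038209), fell from 2.61 ± 0.737 to 0.667 ± 0.155 CPM (-1.96 ± 0.42, adjusted p = 0.018). Kcnh7, a voltage-gated potassium channel gene, changed by -1.83 ± 0.35 (adjusted p = 0.0134). The decreases also included Lcor, Mc5r, Ptar1, Rora, Sytl5, Zfp369, Ago3 and Zbtb16, from -2.61 for Lcor to -1.78 for Zbtb16. With the length and GC correction Zbtb16 remained called (-1.85, adjusted p = 0.00241). Oprm1 kept its log2 fold change of -1.96 but not its call (adjusted p = 0.0951), and Lcor was at -2.38 (adjusted p = 0.112), Grin2a at -1.95 (0.104) and Kcnh7 at -1.28 (0.145).

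Genes induced by glucocorticoids were lower as a group in the libraries labelled cuff. Of 20 members tested, 7 fell, 13 did not pass and none rose (8 fell when adjusted over the list alone), and the median log2 fold change was -0.48 (camera adjusted p = 4.12e-11). Plin4, a lipid droplet protein gene, fell from 30.1 and 22.0 CPM in the libraries labelled sham to 8.07 and 8.32 in those labelled cuff (-1.67 ± 0.18, adjusted p = 0.000246). Pdk4, which inhibits pyruvate dehydrogenase, fell from 31.6 ± 8.71 to 11.7 ± 2.08 CPM (-1.43 ± 0.20, adjusted p = 0.00763), and Hif3a from 24.9 and 23.8 CPM to 12.4 and 13.5 (-0.91 ± 0.15, adjusted p = 0.00855). Besides these and Zbtb16, the genes that fell were Klf9, Errfi1 and Tsc22d3. The log2 mean of the list was also taken relative to each gene's mean over the 4 libraries. It was -0.54 and -0.01 in the libraries labelled cuff and 0.35 and 0.20 in those labelled sham. The second library labelled cuff was thus nearer to the second labelled sham than to the first labelled cuff. The list was lower in each of the fits that left out 1 library (camera adjusted p up to 0.00271) and with the length and GC correction (3.99e-21), but the adjusted p was 0.84 with an estimated correlation. With that correction Plin4 (-1.80, adjusted p = 0.0514), Pdk4 (-1.31, 0.0562) and Hif3a (-0.86, 0.0579) were just over the threshold.

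**Figure D3:**
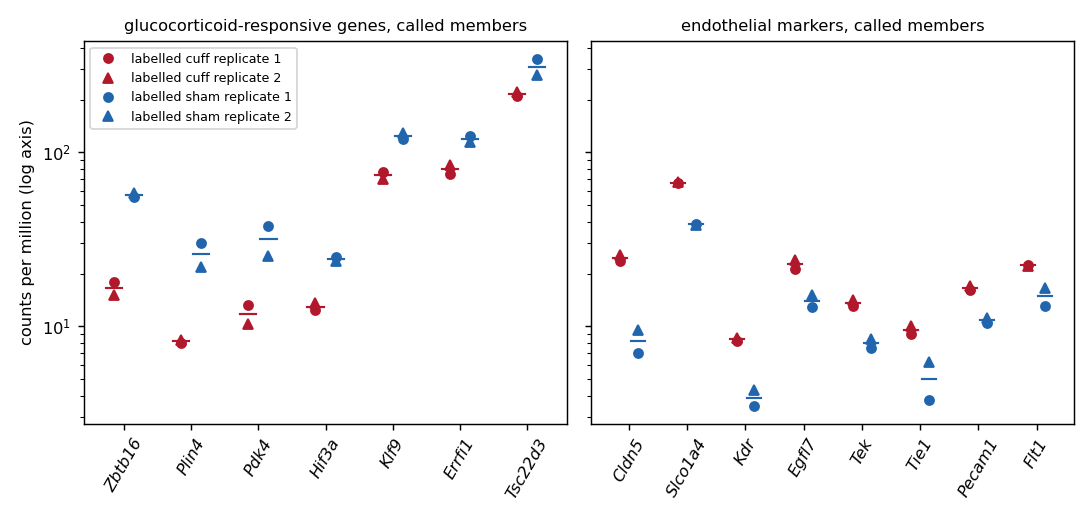
CPM (log axis) of the 7 glucocorticoid-responsive genes called lower (left) and the 8 endothelial genes called higher (right). Each point is 1 library, red for those labelled cuff and blue for those labelled sham, and each line is a group mean (n = 2). For Zbtb16 the libraries labelled cuff were at 18.0 and 15.1 CPM and those labelled sham at 55.6 and 58.4 CPM.

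Markers of blood vessels were higher in the libraries labelled cuff. Among 18 endothelial genes, 8 rose, 10 did not pass and none fell (11 rose when adjusted over the list alone), with a median log2 fold change of 0.61 (camera adjusted p = 6.85e-09). Beside Cldn5, Slco1a4, an organic anion transporter gene of brain endothelium, rose from 38.7 ± 0.385 to 67.0 ± 1.06 CPM (0.79 ± 0.13, adjusted p = 0.00584). Kdr, a receptor for vascular endothelial growth factor, rose by 1.11 ± 0.24 (adjusted p = 0.0173) and Egfl7 by 0.69 ± 0.16 (adjusted p = 0.0258). The other 4 were Pecam1, Flt1, Tek and Tie1. Among 14 pericyte and smooth muscle genes, 3 rose and none fell (5 rose when adjusted over the list alone, camera adjusted p = 4.66e-05). They were Vtn (0.88 ± 0.18, adjusted p = 0.0305), Ndufa4l2 (1.87 ± 0.46, adjusted p = 0.0319) and the platelet-derived growth factor receptor gene Pdgfrb (1.40 ± 0.29, adjusted p = 0.0456), and Myh11 did not pass (0.96 ± 0.29, adjusted p = 0.0696). Cxcl12, a chemokine gene expressed by vessels and meninges, rose from 16.2 ± 1.62 to 35.5 ± 4.22 CPM (1.13 ± 0.15, adjusted p = 0.00139). It was the only called gene among 14 tested cytokine and chemokine genes, a list that was not called (camera adjusted p = 0.557). Both vessel lists stayed called with the length and GC correction (1.16e-12 and 1.53e-05) and so did Cldn5, Slco1a4 and Cxcl12, but Kdr (1.23, adjusted p = 0.0599), Egfl7 (0.48, 0.136), Vtn (0.70, 0.22), Ndufa4l2 (1.68, 0.123) and Pdgfrb (1.31, 0.0779) did not. Neither vessel list was called with an estimated correlation (adjusted p = 0.84 for both).

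Lists of genes from muscle, meninges, white blood cells, bone marrow and ganglia were higher in the libraries labelled cuff. Each list had its highest mean in the second of these libraries. Without it, the meningeal and ganglion lists were not called. All 18 skeletal muscle genes had a positive log2 fold change, with a median of 1.73 (camera adjusted p = 4.41e-05), but none was called. Ckm, the muscle creatine kinase gene, was at 20.1 and 73.1 CPM in the libraries labelled cuff and at 11.2 and 8.47 in those labelled sham. Leptomeningeal and fibroblast genes had a median of 0.89 with 0 of 20 called (camera adjusted p = 0.000169), and Bgn was nearest to the threshold (0.82 ± 0.23, adjusted p = 0.0744). Of 19 lymphocyte and neutrophil genes, 1 was called, Mpo (3 when adjusted over the list alone, camera adjusted p = 3.23e-05). Of 9 adipocyte and bone-marrow stromal genes, 2 were called (4 over the list alone, camera adjusted p = 0.000169), namely Car3 (1.58 ± 0.32, adjusted p = 0.0145) and the osteocalcin gene Bglap, which had 38 and 33 counts against 0 and 4. Of 18 dorsal root ganglion markers 10 could be tested, and 0 were called (3 over the list alone, camera adjusted p = 0.037). The filter left out the rest, among them Scn11a, with 106 counts in the second library labelled cuff and 8 in each other library. The nociceptor sodium channel gene Scn10a had 213 counts in the second library labelled cuff and 0 in the other 3, and was not tested because the filter asks for enough counts in at least 2 libraries. The 16 Schwann cell genes were not called as a list (camera adjusted p = 0.0832), but 7 of 17 alternatives called them higher, among them DESeq2 (0.0277), limma-voom (0.00299) and the fits without the first library labelled cuff (4.77e-30) or the second labelled sham (0.00532). Pmp22, a gene of peripheral myelin, was at 613 and 1412 CPM in the libraries labelled cuff and at 317 and 655 in those labelled sham, and Cdh19 fell (-0.69 ± 0.15, adjusted p = 0.0173), but not with the length and GC correction (-0.41, adjusted p = 0.124). That correction also ended the calls of the ganglion list (0.096), Mpo (2.38, 0.0621), Car3 (1.59, 0.0779) and Bglap (4.13, 0.0994). The log2 fold changes of these genes stayed nearly as large as without it (2.63 for Mpo, 1.58 for Car3 and 4.19 for Bglap). With an estimated correlation none of these lists was called (adjusted p = 0.84, and 0.921 for Schwann cell genes). That correlation was 0.99 for muscle, 0.87 for leptomeningeal and 0.73 for lymphocyte and neutrophil genes, whose members are thus far from separate measurements. It was 0.24 for ganglion and -0.006 for adipocyte and bone-marrow genes. Without the second library labelled cuff, the leptomeningeal and ganglion lists were not called. List means (log2) were also taken relative to each gene's mean over the 4 libraries. In the first library labelled cuff the muscle list was at -0.16, against -0.46 and -0.996 in those labelled sham. The adipocyte and bone-marrow list was at 0.43 against -0.73 and -0.45, and the lymphocyte and neutrophil list at -0.06 against -0.89 and -0.26. The ganglion list was at 0.04 against -0.42 and -0.35, and the leptomeningeal list at -0.17 against -0.80 and -0.03. In the second library labelled cuff the muscle list was at 1.62 and the adipocyte and bone-marrow list at 0.75. The lymphocyte and neutrophil, ganglion and leptomeningeal lists were at 1.21, 0.73 and 1.00 there.

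**Figure D4:**
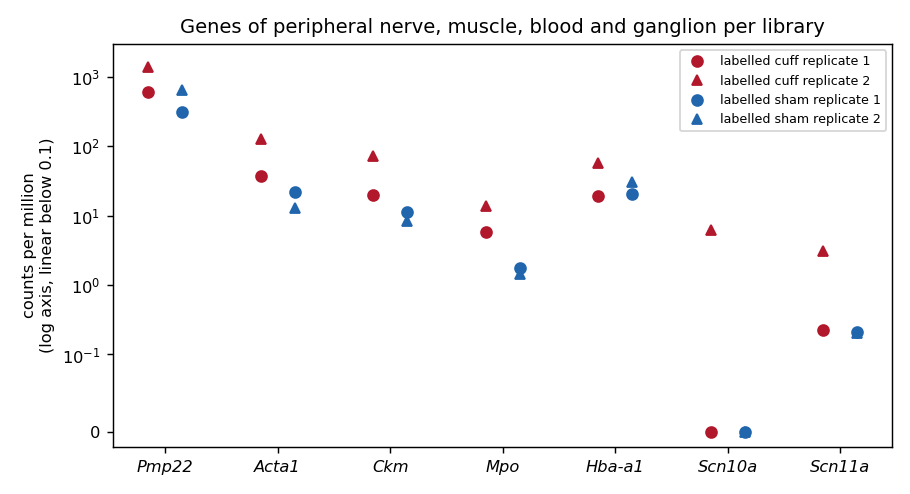
CPM in each of the 4 libraries (log axis, linear below 0.1) of genes typical of peripheral nerve (Pmp22), muscle (Acta1, Ckm), neutrophils (Mpo), red blood cells (Hba-a1) and ganglion nociceptors (Scn10a, Scn11a). The second library labelled cuff was highest for each of the 7 genes, with 1412 CPM of Pmp22 and 6.24 CPM of Scn10a.

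Genes of inhibitory transmission were lower as a list in the libraries labelled cuff, and single genes of other neuronal receptors and channels fell. Of 26 GABAergic and glycinergic genes, 6 fell, 20 did not pass and none rose (9 fell when adjusted over the list alone, camera adjusted p = 0.000113). Examples are the GABA-A receptor subunit genes Gabrb2 (-0.68 ± 0.13, adjusted p = 0.0134), which averaged 94.8 ± 1.33 CPM in the libraries labelled sham and 59.3 ± 6.65 in those labelled cuff, Gabrb1 (-1.17 ± 0.23, adjusted p = 0.0147) and Gabra2 (-0.61 ± 0.14, adjusted p = 0.029). The genes that fell also included the glycine receptor subunit gene Glra3 and the glycine transporter gene Slc6a5. Of 38 voltage-gated channel genes, 2 fell (camera adjusted p = 0.0135). These were Kcnq3 (-1.75 ± 0.24, adjusted p = 0.0042), a subunit of the M-type potassium channel, and the sodium channel gene Scn1a (-0.62 ± 0.14, adjusted p = 0.0225), while Scn2a (-0.47) and Kcnma1 (-0.95) did not pass. The list of 30 glutamate receptor genes was just over the threshold (camera adjusted p = 0.0548; lower at 0.0485 with RLE scaling, 0.0388 with DESeq2 and 2.38e-05 without the first library labelled sham), and 3 of its members fell: Grin2a, Gria2 (-0.61 ± 0.15, adjusted p = 0.0286) and Grin3a (-0.79 ± 0.19, adjusted p = 0.0299). Among 21 monoamine receptor genes the serotonin receptor gene Htr2a (-1.52 ± 0.27, adjusted p = 0.0101) and the adrenergic receptor gene Adra1a (-0.93 ± 0.22, adjusted p = 0.0286) fell. Oprm1 was the only called gene of 18 opioid and cannabinoid genes, and neither of these lists was called (camera adjusted p = 0.187 and 0.814). With the length and GC correction the log2 fold change became -0.51 for Gabrb2, -0.70 for Gabrb1, -0.22 for Gabra2, -0.31 for Scn1a and -0.05 for Gria2. It became -1.38 for Kcnq3, -1.22 for Htr2a, -1.95 for Grin2a, -0.66 for Grin3a and -0.91 for Adra1a, and none of these receptor and channel genes stayed called. The inhibitory list kept its call (camera adjusted p = 3.37e-05) and the channel list lost it (0.078), as it did without the second library labelled sham (0.99), and neither was called with an estimated correlation (adjusted p = 0.84).

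**Figure D5:**
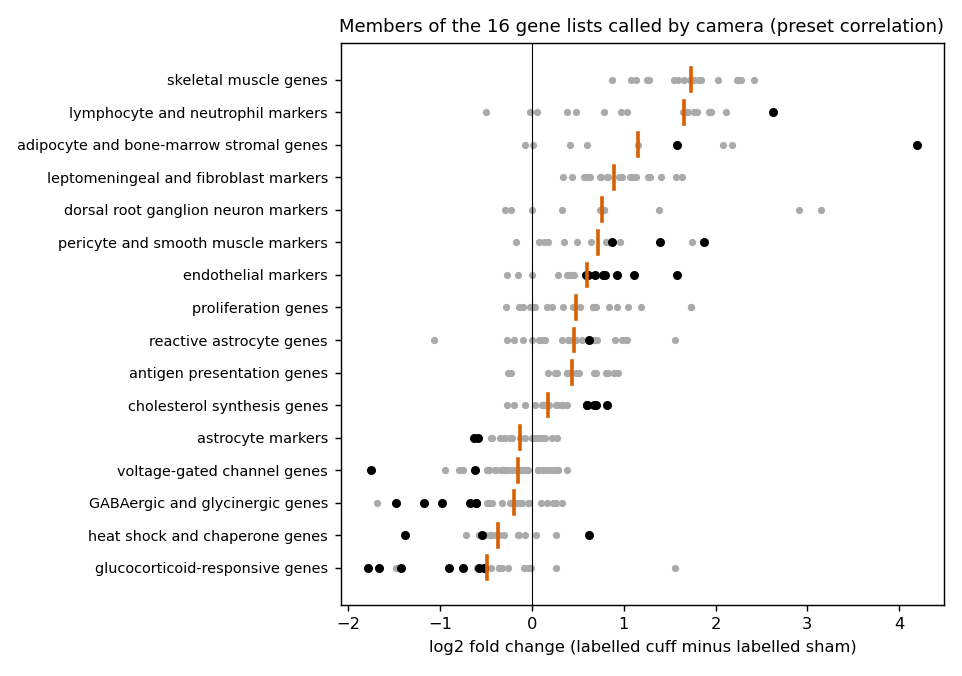
Log2 fold changes (labelled cuff minus labelled sham) of the tested members of the 16 lists called by camera with the preset correlation of 0.01. Black points are called genes, grey points are genes that were not called, and orange bars are list medians. The medians run from -0.48 for glucocorticoid-responsive genes to 1.73 for skeletal muscle genes.

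Genes that mark nerve injury were not called as a list, nor were those of microglia without the length and GC correction, while lists of reactive astrocyte and antigen presentation genes were higher in the libraries labelled cuff. Of 24 nerve injury genes of axotomised neurons 1 rose, the small heat shock protein gene Hspb1 (0.62 ± 0.15, adjusted p = 0.0325), and the list was not called (camera adjusted p = 0.832). The median log2 fold change of these genes was -0.05 and their mean 0.19, so that median and test differed in sign. None of 25 microglia and macrophage genes (camera adjusted p = 0.325) and none of 24 reactive microglia genes (0.45) was called. The first of these lists was lower with the length and GC correction (0.0438), and DESeq2 and edgeR's likelihood ratio test each called 1 gene lower in the first and 1 higher in the second. The genes nearest to the threshold were Ctss (-0.47 ± 0.15, adjusted p = 0.0754) and P2ry12 (-0.40 ± 0.18, adjusted p = 0.213) in the first list, and Cybb (1.32 ± 0.40, adjusted p = 0.104) and Clec7a (1.05 ± 0.37, adjusted p = 0.106) in the second. Astrocyte markers were lower as a list (camera adjusted p = 0.037), with 2 of 19 called: Aqp4, the water channel of astrocyte endfeet (-0.63 ± 0.15, adjusted p = 0.0248), and Ppp1r3c (-0.59 ± 0.14, adjusted p = 0.0309). These were at -0.35 (adjusted p = 0.119) and -0.51 (0.0804) with the length and GC correction, under which Hspb1 was at 0.44 (0.13) and the antigen presentation list below was not called (0.197). The list of reactive astrocyte genes was higher (camera adjusted p = 0.0135) with 1 of 25 called, again Hspb1. Antigen presentation genes were higher as a list (camera adjusted p = 0.03) with 0 of 16 called. Without the second library labelled cuff none of these 3 lists was called (adjusted p = 0.0774, 0.077 and 0.949), nor were they with an estimated correlation (adjusted p = 0.84 for each). The astrocyte list also lost its call without the first library labelled cuff (0.0678) or the first labelled sham (0.219), with upper quartile scaling (0.0521) and with limma-voom (0.0546), and the antigen presentation list without the first labelled sham (0.189). Complement (0.0867), interferon-stimulated (0.502) and dorsal horn neuropeptide genes (0.986) were not called as lists, and the complement gene C2 rose (1.61 ± 0.40, adjusted p = 0.0349; 1.49 and 0.147 with the length and GC correction). The complement list was higher with the replicate block (0.0159) and without the first library labelled cuff (0.00927).

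A panel of 24 genes often measured in the cord after nerve injury was fixed before the data were examined. Of the 22 that could be tested, Oprm1 was lower and the other 21 did not pass, 5 of them with a positive and 16 with a negative log2 fold change. The 6 with the highest mean CPM were Gfap (1127 ± 174 CPM in the libraries labelled cuff and 1284 ± 243 in those labelled sham, log2 fold change -0.19 ± 0.16), the potassium chloride cotransporter gene Slc12a5 (661 ± 51.8 and 589 ± 62.9, 0.16 ± 0.14), Gad1 (191 ± 9.11 and 196 ± 13.7, -0.04 ± 0.13), Penk (176 ± 3.0 and 162 ± 9.09, 0.11 ± 0.13), Gad2 (124 ± 3.90 and 145 ± 28.7, -0.23 ± 0.14) and Csf1r (78.0 ± 4.61 and 93.4 ± 0.913, -0.26 ± 0.13). Their adjusted p-values lay between 0.25 for Csf1r and 0.90 for Gad1. Of these 6 genes only Csf1r passed in any alternative, as lower in 1 of 19. Il1b and Tnf had at most 13 counts in any library and were not tested.

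Cholesterol synthesis genes were higher in the libraries labelled cuff. Of 22 genes, 5 rose and none fell (6 rose when adjusted over the list alone), with a median log2 fold change of 0.18 (camera adjusted p = 4.66e-05). The enzyme genes Dhcr7 (0.68 ± 0.13, adjusted p = 0.012), Mvd (0.70 ± 0.14, adjusted p = 0.0134), Mvk (0.60 ± 0.14, adjusted p = 0.0249) and Tm7sf2 were among the genes that rose. Heat shock and chaperone genes were lower as a list (camera adjusted p = 0.000249). Hspa1b (-1.38 ± 0.30, adjusted p = 0.0175) and Pdia4 (-0.54 ± 0.15, adjusted p = 0.0466) fell, Hspb1 rose, and 14 of 17 did not pass (10 fell and 1 rose when adjusted over the list alone). Hspa1b has a near-identical neighbour, Hspa1a, so that its counts are uncertain. Both lists kept their calls with the length and GC correction (1.48e-09 and 2.68e-08), under which none of their members was called, and both had an adjusted p of 0.84 with an estimated correlation. The heat shock list was not called without the first library labelled sham (0.189). Proliferation genes were higher as a list (camera adjusted p = 0.0135; 0.84 with an estimated correlation) with 0 of 20 called, and Birc5 was nearest to the threshold (1.19 ± 0.38, adjusted p = 0.0808). That list was not called without the second library labelled cuff (0.373) or the first labelled sham (0.0822).

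The remaining lists were not called, although some were in single alternatives. Clock genes had an adjusted p of 0.832, with Clock lower (-0.88 ± 0.15, adjusted p = 0.00855) and Nr1d1 higher (0.57 ± 0.14, adjusted p = 0.0363). Oligodendrocyte precursor markers had 0.832, with Sox10 higher (0.54 ± 0.13, adjusted p = 0.0299) and Ptprz1 lower (-0.61 ± 0.15, adjusted p = 0.038). Immediate early genes had 0.125, with Ier5 higher (0.61 ± 0.16, adjusted p = 0.0446), and replication-dependent histone genes 0.204, with H1f2 higher (0.64 ± 0.16, adjusted p = 0.0311). Motor neuron and cholinergic genes had 0.999, with Mmp9 higher (0.88 ± 0.19, adjusted p = 0.0295), and pan-neuronal genes 0.999, with Elavl4 lower (-0.50 ± 0.14, adjusted p = 0.05, just under the threshold). With the length and GC correction none of these genes was called, and the log2 fold change was -0.46 for Clock, 0.33 for Nr1d1, 0.23 for Sox10, -0.34 for Ptprz1, 0.51 for Ier5, 0.51 for H1f2, 0.68 for Mmp9 and -0.22 for Elavl4. No member was called among oligodendrocyte and myelin genes (0.139), ependymal genes (0.502), erythroid genes (0.438), patterning genes of spinal levels (0.269), mitochondrially encoded genes (0.993), cytosolic ribosomal protein genes (0.182) and nuclear respiratory chain genes (0.598). Without the second library labelled cuff the oligodendrocyte list was higher (0.0102), the ependymal list lower (0.00703) and the mitochondrially encoded list higher (0.0437), and without the first labelled sham the oligodendrocyte list was higher (0.00095). With the Schwann cell list as a covariate these 3 lists were called in the same directions (4.88e-05, 0.048 and 0.000106). Erythroid genes were higher without the first library labelled cuff (8.65e-13), immediate early genes without the second labelled sham (0.0443) and histone genes with the Schwann covariate (0.0467).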

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

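The fits corrected for transcript length and GC content, the fit of genes with a transcript length only and the fit with the Schwann cell list as a covariate were chosen after the data were seen. As given in the report, 696 genes were called, 195 higher and 501 lower in the libraries labelled cuff. None of the tested calls changed direction in any alternative. Upper quartile scaling called 299 higher genes (64.4% of 841 calls were lower, against 72.0% as reported), DESeq2 called 1071 genes, 824 of them lower, and edgeR's likelihood ratio test 1046 with 341 higher. The dispersion prior that is not robust called 237 (60 higher, 177 lower) and the fit without a filter 1292 (443 and 849). RLE scaling, limma-voom, a mean count of at least 10 and the fit of genes with a length gave counts within 1.5 times the reported ones. Leaving out 1 library, which leaves a lone sample assumed to vary like the other group, gave between 0 and 1928 called genes, between 0 and 714 higher and between 0 and 1214 lower. Without the second labelled cuff 26.9% of the calls were lower. The lowest counts came without the first library labelled sham, where the median prior degrees of freedom were 5.70 (15.8 with all libraries). The cause of these counts was not tested. The correction for length and GC called 17 genes (7 higher, 10 lower), the same correction with the likelihood ratio test 682 with 293 higher, and with the replicate block 65 (44 higher, 21 lower). The Schwann cell list as a covariate left 42 (17 and 25), with 1 residual degree of freedom less. Of the lists, 16 were called as reported, 8 when the genes of other cell types and mitochondria were left out before scaling (7 of the 16 had no gene left, and the astrocyte list was at an adjusted p of 0.0525), and 0 with an estimated correlation. Replicate numbers pair nothing in the labels: with the replicate block 554 genes were called, 309 of them lower, and the deviations of same-numbered libraries correlated at 0.116 across genes.

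Genes and lists that changed sign were not called as reported, except the antigen presentation list (adjusted p = 0.924 in the other direction with the Schwann covariate). The log2 fold change of Gad1 lay between -0.138 and 0.0308 with 1 library left out and turned positive without the second labelled cuff (0.0076) and the second labelled sham. With the length and GC correction, alone, with the likelihood ratio test and with the block, that of Gad1 was 0.0315, 0.0315 and 0.0339, that of Gad2 0.0339, 0.034 and 0.0424, and that of Slc12a5 -0.00075, -0.00075 and -0.00084. Gfap lay between -0.409 and 0.0027 with 1 library left out, the highest without the first labelled sham, and was at 0.0594 with the Schwann covariate. With 1 library left out the adjusted p of cytosolic ribosomal genes lay between 4.08e-07 and 0.730 and that of respiratory chain genes between 0.000367 and 0.993. Both turned lower without the second library labelled sham (0.0339 and 0.0182), and erythroid genes did so with the Schwann covariate (0.0467). The cause was not tested for these. Depth limited genes near 1 CPM, about 33 to 39 counts per library, and the self-test recovered 25.4% of 1.5-fold changes, so that a gene not called may still differ by that much.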

Other observations

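The tests of nerve root and muscle tissue and of other splits, the share of lower genes with the length and GC correction (in place of a count of lower calls written before), the test with the prior degrees of freedom of the uncorrected fit, and the part of the length and GC test that uses the median of the endothelial genes, were chosen after the results were seen. The genes of this paragraph were picked after their values were seen, and no group of them was tested. Of genes known from bone, Mmp13 had 101 and 22 counts in the libraries labelled cuff against 4 and 4 in those labelled sham, Bglap2 34 and 42 against 4 and 0, and Atp6v0d2, an osteoclast proton pump gene, 12 and 37 against 0 and 0. Rbp4 (log2 fold change 1.28 ± 0.24, adjusted p = 0.0105), the anion transporter gene Slc22a8 (1.39 ± 0.26, adjusted p = 0.0203), the endothelial gene Eng (1.01 ± 0.19, adjusted p = 0.012) and Cirbp (0.76 ± 0.14, adjusted p = 0.0103) rose. Dio2, which activates thyroid hormone, fell by 0.99 on the log2 scale (adjusted p = 0.00212). Of the lower calls with a known chromosome 8.78% were X-linked, against 1.03% of the higher calls and 3.44% of tested genes.

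The sample titles and the file names give opposite conditions for all 4 libraries. If the titles were exchanged, genes of axotomised neurons might be lower in the libraries labelled cuff, but the list test gave an adjusted p of 0.832 and decided nothing, and Hspb1 was its only called gene. Atf3, a marker of axotomised neurons, was at 1.09 ± 0.123 CPM in the libraries labelled cuff and 1.44 ± 0.414 in those labelled sham (adjusted p = 0.628). The 2 readings cannot be told apart from these counts, because no gene in them was set by the surgery to a known level. Every direction in the text rests on the titles.

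More genes were lower than higher, 501 against 195, but without the second library labelled cuff 58 were lower and 158 higher. Part of the excess ran with transcript length and GC content. On the same genes the share of lower genes among likelihood ratio calls was 67.7% (691 lower, 329 higher) without and 57.0% (389 lower, 293 higher) with the correction. The correction was fitted on these 4 libraries and removes any difference that follows length or GC, whatever its origin. It therefore cannot tell a technical trend from a true fall of long genes of low GC content. The 486 lower calls with a length moved from a median log2 fold change of -0.71 (median SE 0.155) to -0.45 (0.110), and 10 were still called, or 283 with the prior degrees of freedom of the uncorrected fit. Lower calls outnumbered higher ones with each scaling: 501 against 195 with TMM, 479 against 159 with RLE and 542 against 299 with upper quartile scaling. An excess of lower calls thus remained whichever of these scalings was chosen. The share of lower calls was 64.4% with upper quartile, between the bounds set beforehand, and 75.1% with RLE scaling. The test of scaling therefore decided nothing, and scaling stays open. With 3 splits of the 4 libraries, of which 1 gave as many calls (the real one with 696, the highest other 0), no share under 0.05 can be had.

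Endothelial genes were higher in the libraries labelled cuff. The length and GC trend is argued against as the whole cause, since the 8 called genes went from a median of 0.78 (median SE 0.173) to 0.81 (0.142) with the correction. The rule written before, that under 50% of the 8 stay called, was however met and would have given the opposite answer, since 2 stayed called (7 with the prior degrees of freedom of the uncorrected fit). Muscle and nerve root tissue stay open: the slope of the endothelial list mean within groups gave 13.6% of the group difference on the muscle list (95% interval -483 to 510) and 25.3% on the Schwann cell list (-69.8 to 120), with 1 residual degree of freedom. The adipocyte and bone-marrow list ran alongside the endothelial list. Relative to each gene's mean over the 4 libraries, its log2 mean was 0.43 and 0.75 in the libraries labelled cuff and -0.73 and -0.45 in those labelled sham. The endothelial list was at 0.20 and 0.38 against -0.41 and -0.16. Whether these lists share a source was not tested. A change of vessels with the surgery, or a different share of vessel and meningeal tissue in the dissected pieces, may underlie the endothelial rise, and neither was tested.

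The 7 called glucocorticoid-responsive genes had a median log2 fold change of -0.86 (median SE 0.117) with the length and GC correction against -0.91 (0.144) without it, with 2 of them still called and all 7 called by the likelihood ratio test with the same correction. The lower calls as a whole moved further, from -0.71 to -0.45. For these 7 genes the length and GC trend is thus argued against as the whole cause, and no other explanation of their fall was tested.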
